A study of Mus musculus with 2 samples.

How the data were processed

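The series measured messenger RNA in single cells sorted from the whole brain of adult mice, with the 10x Genomics Chromium 3′ v3.1 kit. Per the labels, the sorted populations were mural cells and fibroblasts, endothelial cells, astrocytes, border-associated macrophages (BAMs, the macrophages outside the parenchyma) and microglia, each taken by its own surface markers. 1 library came from mice labelled IL34LacZ/+ and 1 from mice labelled IL34LacZ/LacZ, and these are called the heterozygous-labelled and the homozygous-labelled library here. The number, sex and age in weeks of the animals behind each library are not given in the sources used here, and neither are the proportions in which the sorted populations were loaded.

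The authors' deposited matrices hold UMI counts per gene and barcode, made with Cell Ranger 5.0.0 per the file headers, on mouse genome build GRCm38.p6 (mm10) per the labels. All values were whole numbers and the lowest total per barcode was 500 UMIs in each library, although the rule by which barcodes were kept is not given in the sources used here. The heterozygous-labelled matrix holds 17168 barcodes with 87394167 UMIs, and the homozygous-labelled matrix holds 18858 barcodes with 95505407 UMIs. Of the 25827 genes in the matrices, 25651 had their identifier in the GENCODE vM21 annotation (99.3%), which gave the gene positions. 4 long non-coding RNAs (Xist, Malat1, Neat1 and Meg3) and the lacZ reporter are not among the features. No cell annotation was used here, so cell types were rebuilt from marker genes and are written as "endothelial-like" and so on.

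Cells were kept with at least 1000 UMIs, at least 500 genes and at most 10% mitochondrial UMIs. Doublets were called per library with Scrublet at an expected rate of 10% and removed. It called 1145 of the heterozygous-labelled barcodes (6.67%) and 1363 of the homozygous-labelled ones (7.23%). This left 8188 cells (47.7% of barcodes) and 9553 cells (50.7%). Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes and 30 principal components were taken over both libraries without batch integration, and cells were grouped by the Leiden method at resolution 1 on a shared-neighbour graph of 20 nearest neighbours with seed 1. The software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, scanpy 1.11.5, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16.

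The clustering gave 31 clusters. Clusters were named from marker lists for resident brain, vascular and blood cell types. A name needed a mean log2 marker enrichment of at least 1 over the median cluster, at least 3 markers at least 2-fold enriched, a lead of at least 0.5 over the next type, and its own markers ahead of those of other types among the 10 or 50 leading genes. The marker lists were fixed before the data were examined, whereas these naming thresholds were set afterwards. 4 clusters stayed without a name and outside every class, with 12.4% of the heterozygous-labelled and 14.1% of the homozygous-labelled cells. Mural-like cells were clustered again by themselves to look for pericyte and smooth muscle subsets.

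For each class, UMIs were summed over its cells in each library and given as CPM, the usual scaling by the total UMIs of the class and library, with exact Poisson 95% intervals. Each ratio is homozygous-labelled over heterozygous-labelled, with an exact conditional binomial 95% interval, and shares of cells carry exact Clopper-Pearson 95% intervals. A count of 0 is given with the limit of 3 counts. With 1 library per genotype there is no replicate, no test between genotypes was possible and no p-value is given. The intervals cover counting error within these libraries only, so they say nothing of the spread between animals, sorts or library preparations. A gene was counted as differing when it had at least 100 UMIs over both libraries, a ratio of at least 2 in either direction and an interval without 1. Such counts describe these 2 libraries.

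Gene lists, the filters above, the comparisons and the rule for naming genes were fixed before the data were examined. The 35 lists fall into groups. Lists computed in every class are the IL-34 and CSF1 axis, interferon response, MHC class I presentation, dissociation and immediate-early genes, hypoxia and glycolysis, oxidative phosphorylation, cell cycle and sex-linked genes. Endothelial lists are blood-brain barrier transporters, endothelial junctions and basement membrane, Wnt target genes, endothelial activation, caveolae and transcytosis, angiogenesis and tip cell, vasoactive signalling, arterial identity and venous identity. Mural lists are contractile apparatus, pericyte identity, mural receptors and vasoactive signalling, and mural matrix. Fibroblast lists are matrix, myofibroblast and TGF-beta response, and transporters and trophic factors. Astrocyte lists are endfoot and junction, reactivity, and trophic and synaptogenic factors. Macrophage lists are microglia homeostatic, disease-associated microglia, MHC class II presentation, cytokines and chemokines, complement, lysosome and endocytosis, perivascular macrophage identity, and vascular and trophic factors. For each list the median log2 ratio of members with at least 20 UMIs was set against 10000 random lists of the same size matched on expression in 20 bins. A list is said to stand apart when its percentile is at most 2.5 or at least 97.5. Intervals over resampled cells are 95% intervals from drawing the cells of each library again with replacement.

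Named genes are the leading 10 in each direction per class among genes with at least 100 UMIs, a ratio of at least 1.5 whose interval excludes 1, a level of at least 20% of the highest named class as a guard against free RNA, and the same direction in every cluster of the class with at least 200 cells in each library. They were ranked by the interval bound nearest 1, and up to 3 members per direction of each list are named as well. Mitochondrial, ribosomal protein, haemoglobin, predicted, sex-linked and dissociation-list genes were left out of the ranking. Classes with fewer than 100 cells in a library were not ranked. Where the text gives the part of a gene's UMIs found in 1 cell, it is out of the UMIs of that class in the library where the gene was higher. For 1 member of the interferon list, its own value is not reported here, while the list medians and counts include it. Genes and groups outside this rule that the text names were picked after their values were seen.

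The procedure was tested on simulated data, in which 200 genes per class were given a known fold. Counts were drawn as independent Poisson counts, without spread between cells, genes moving together or shifts between libraries. The simulation thus checks the rules under counting error alone and not how they behave in these libraries. At 1.25-fold no changed gene was called in any class (0%). At 2.5-fold the share called was 92.5% in endothelial-like, 79.1% in mural-like, 89.6% in fibroblast-like, 88.1% in microglia-like and 95.5% in BAM-like settings, and at 4-fold it was 92.4%, 71.2%, 92.4%, 86.4% and 95.5%. Unchanged genes were called 0 times, and 1 time for BAM-like cells. Intervals held the true ratio for 95.8%, 95.7%, 95.6%, 96.1% and 95.4% of genes in that order. Of 100 random lists, 3 stood apart in each class and 5 in mural-like cells, and a list of raised genes reached percentile 100 in each.

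Alternatives were run on the UMI minimum (500 and 2000), the mitochondrial limit (5% and 20%), doublets kept, Leiden resolution (0.5 and 2), scaling (TMM from edgeR, median of ratios, totals without mitochondrial and ribosomal protein genes), equal weight per cell, cells thinned to 2000 UMIs (cells under that left out), averaging over clusters, the gene minimum (50 and 500 UMIs) and the list member minimum (100 UMIs). Those added after values had been seen leave out the subtype markers from the variable genes, the BAM-like cluster led by interferon genes, the mural-like subcluster that mixes in endothelial markers, the fenestrated-like endothelial cluster, genes under a free RNA guard over all clusters, and the cell with most UMIs of each gene. Sequence reads were not used here, so the structure of the targeted allele was not examined.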

Results

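The data are 2 single-cell libraries of sorted brain macrophages and vascular cells, 1 from mice carrying the lacZ allele of Il34 on 1 chromosome (heterozygous-labelled) and 1 from mice carrying it on both (homozygous-labelled). The title of the series names perivascular macrophages that depend on interleukin-34, the cytokine encoded by Il34 that signals, like CSF1, through the receptor CSF1R. The heterozygous-labelled library held 87394167 UMIs in 17168 barcodes and the homozygous-labelled library 95505407 UMIs in 18858 barcodes. After filtering, 8188 and 9553 cells remained, with a median of 3539.5 and 3678 UMIs.

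All 6 sorted populations were found by their markers. Endothelial-like cells numbered 1826 in the heterozygous-labelled and 1723 in the homozygous-labelled library, BAM-like cells 1874 and 1802, microglia-like cells 749 and 1029, fibroblast-like cells 710 and 987, and mural-like cells 184 and 343. Astrocyte-like cells were too few for any expression comparison, with 16 and 15 cells. Median UMIs per cell were 2100.5 and 2081 in endothelial-like, 1686.5 and 1858 in mural-like, 5508 and 5409 in fibroblast-like, 6567 and 6391 in astrocyte-like, 2685 and 3088 in microglia-like and 3531 and 3937.5 in BAM-like cells. Median mitochondrial shares in the same order were 5.02% and 5.08%, 6.70% and 6.68%, 7.23% and 6.95%, 7.51% and 7.44%, 2.91% and 2.81%, and 5.11% and 4.51%. Mural-like, astrocyte-like and microglia-like cells each formed 1 cluster (100%). The largest cluster held 47.6% and 43.3% of endothelial-like, 49.9% and 38.6% of fibroblast-like and 45.1% and 45.5% of BAM-like cells.

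The first comparison asks where Il34 is expressed and whether its level parts the genotypes. Il34 was highest in mural-like cells, at 124 CPM (94.0 to 160) in the heterozygous-labelled and 106 CPM (85.0 to 131) in the homozygous-labelled library, and it was lower in fibroblast-like cells (27.8 and 25.2 CPM) and neuron-like cells (26.0 and 18.1 CPM). No drop in the homozygous-labelled library was detectable at this depth in those classes, with ratios of 0.857 (0.608 to 1.22), 0.905 (0.713 to 1.15) and 0.696 (0.431 to 1.13). An unnamed cluster close to fibroblasts was the exception, at 9.25 and 4.61 CPM with a ratio of 0.498 (0.289 to 0.845) on 37 and 26 UMIs. Endothelial-like cells gave 6 and 8 UMIs of Il34, BAM-like cells 4 and 8, and microglia-like cells 1 and 5. The gene (ENSMUSG00000031750) lies on the minus strand of chromosome 8 at 110741829 to 110805924 in GRCm38, and its annotated transcript of 7 exons ends in a 3′ untranslated region of 442 bp, near which a 3′ kit takes its tags. The labels do not say which part of the gene the allele removes. A tag outside that part would leave the genotype unchecked, so these levels neither verify nor contradict the labels.

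Csf1, the other ligand of CSF1R, was higher in the homozygous-labelled microglia-like cells, at 39.7 against 23.1 CPM (1.719-fold, 1.249 to 2.396). It was also higher in endothelial-like cells (69.7 against 56.3 CPM, 1.24-fold, 1.05 to 1.46) and fibroblast-like cells (62.8 against 53.0 CPM, 1.19-fold, 1.01 to 1.40), but its log2 ratio turned in the former when averaged over clusters (-0.15) and in the latter at a mitochondrial limit of 5% (-0.21). BAM-like cells differed within counting error (8.90 against 7.73 CPM, 1.15-fold, 0.814 to 1.63). So did mural-like cells, on 27 UMIs against 8 in the heterozygous-labelled library (1.93-fold, 0.852 to 4.91). Csf1r itself was at the same level in microglia-like cells of both libraries, at 3102 and 3106 CPM (ratio 1.001, 0.972 to 1.03), and close in BAM-like cells, at 1829 and 1929 CPM (ratio 1.05, 1.03 to 1.08). Its UMIs were also more frequent in endothelial-like cells (72.97 against 45.5 CPM, 1.60-fold, 1.35 to 1.91) and mural-like cells (69.5 against 38.4 CPM, 1.81-fold, 1.05 to 3.27), on 57 against 18 UMIs in the latter. Those levels lie far under 20% of the level in microglia-like cells, the limit used here against free RNA, so they are not read as expression by vascular cells. The median ratio of the 5-gene axis list was 1.09 in endothelial-like (percentile 75.4), 1.10 in fibroblast-like (79.6) and 1.05 in BAM-like cells (63.4). It was 1.69 in microglia-like (99.7) and 1.81 in mural-like cells (99.6), each on 3 measured members. The microglia-like median is the ratio of Ptprz1 or Sdc1, the remaining members of the list, and not of Csf1 or Csf1r. In microglia-like cells the list was no longer apart at a mitochondrial limit of 5% (0.49 on the log2 scale) or with equal weight per cell (0.39), 2 of 11 alternatives. The mural-like median is the ratio of Csf1r itself, below that limit, which turned at a mitochondrial limit of 20% (-0.27 on the log2 scale), and the list kept its standing there in 3 of 8 alternatives. It was no longer apart without a subcluster that mixes in endothelial markers (0.58 on the log2 scale). Csf1 (ENSMUSG00000014599) lies on chromosome 3 at 107741048 to 107760469 and Csf1r (ENSMUSG00000024621) on chromosome 18 at 61100598 to 61132149.

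**Figure D1:**
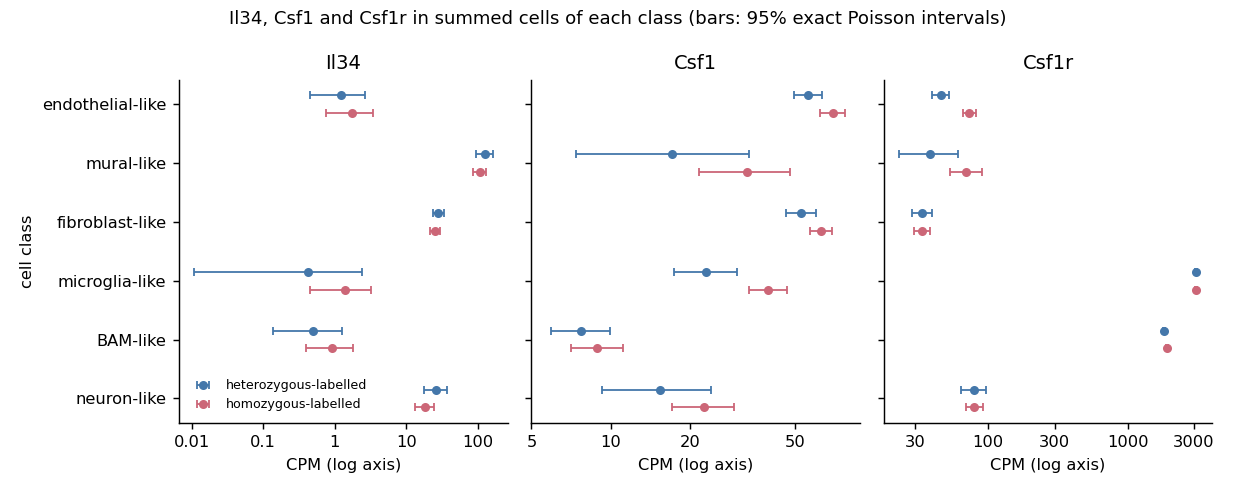
Il34, Csf1 and Csf1r in CPM (log axis) by cell class, blue for the heterozygous-labelled and red for the homozygous-labelled library, with 95% exact Poisson intervals. Il34 is highest in mural-like cells (124 and 106 CPM) and Csf1r in microglia-like cells (3102 and 3106 CPM).

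The second comparison asks whether the makeup of the sorted cells differs between the libraries. Within the macrophages, BAM-like cells made up 71.4% (69.7 to 73.2) of microglia-like and BAM-like cells together in the heterozygous-labelled library and 63.7% (61.8 to 65.4) in the homozygous-labelled library. Among BAM-like cells the clusters named Lyve1-high made up 81.6% (79.8 to 83.3) and 74.3% (72.2 to 76.3). Their marker set includes Lyve1, a hyaluronan receptor of perivascular and leptomeningeal macrophages. At a mitochondrial limit of 5% the difference lay within counting error, at 76.3% (73.4 to 79.1) and 74.3% (71.5 to 76.9). The largest of these clusters, with Lyve1 among its leading genes, held 45.1% and 45.5% of BAM-like cells. The others were led by Wfdc17 and Ccl8 (499 and 401 cells) and by interferon genes (185 and 118 cells). The lower Lyve1-high share thus lay outside the cluster led by Lyve1. The cluster with high MHC class II genes made up 17.6% (15.9 to 19.4) and 24.5% (22.5 to 26.5). Microglia and BAMs were taken by separate gates, so their ratio follows how many cells of each were sorted. The subsets of BAM-like cells come from 1 gate, but at a mitochondrial limit of 20%, at Leiden resolution 0.5 or without subtype markers the MHC class II cluster lay among the unnamed clusters and gave no share.

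Among endothelial-like cells the fenestrated-like cluster, led by the diaphragm gene Plvap, was smaller in the homozygous-labelled library, at 8.13% (6.88 to 9.52) against 11.7% (10.2 to 13.2). Choroid plexus epithelial-like cells, whose tissue holds fenestrated vessels, also made up less of that library, at 4.83% against 10.6% of all cells. Capillary-like cells made up 72.3% (70.2 to 74.4) and 74.9% (72.8 to 76.9), venous-like cells 9.91% (8.58 to 11.4) and 11.8% (10.4 to 13.5), and arterial-like cells 6.08% (5.03 to 7.27) and 5.17% (4.17 to 6.32), all within overlapping intervals. At a mitochondrial limit of 5% the log2 ratio of the capillary-like share moved from 0.050 to 0.12, beyond its counting interval. No mural-like subcluster met the naming rule for smooth muscle under the main settings, so no pericyte share is given there. Subclusters leaning to smooth muscle did form, by mean log2 marker enrichment over all mural-like cells. In subclusters named pericyte, smooth muscle scores reached 0.476 and 0.0927 against pericyte scores of -0.588 and -0.977. The subcluster mixed with endothelial markers had 0.797 against -2.09. Where a smooth muscle subcluster was named, the pericyte share is out of the mural-like cells named pericyte or smooth muscle, with mixed subclusters left out. It was 86.5% and 92.9% from 500 UMIs per cell, and 83.8% and 89.4% with doublets kept. Every subcluster that met no other naming rule was named pericyte, so the share is a loose measure of pericytes. Of all cells, endothelial-like cells made up 22.3% and 18.0%, BAM-like 22.9% and 18.9%, microglia-like 9.15% and 10.8%, fibroblast-like 8.67% and 10.3%, mural-like 2.25% and 3.59% and astrocyte-like 0.195% and 0.157%. These shares of all cells follow the sort and are given as description.

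**Figure D2:**
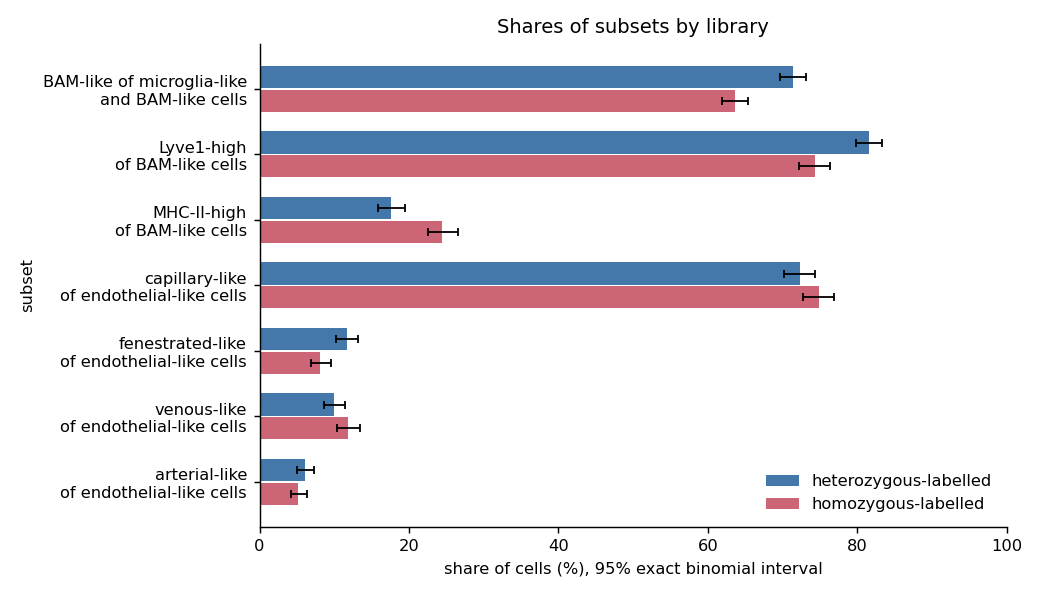
Share of cells (%) in each subset, blue for the heterozygous-labelled and red for the homozygous-labelled library, with 95% exact binomial intervals. BAM-like cells go from 71.4% to 63.7% of macrophages, and MHC-II-high cells from 17.6% to 24.5% of BAM-like cells.

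BAM-like cells of the homozygous-labelled library held fewer transcripts of interferon-response genes and more of antigen presentation genes. The interferon list had a median ratio of 0.707 (percentile 0 among random lists), and 6 of 16 measured members were at least 1.5-fold lower with none higher by that much. Rsad2, an antiviral enzyme, was at 34.6 against 86.9 CPM (ratio 0.398, 0.346 to 0.456), Isg15, a ubiquitin-like modifier, at 75.3 against 166 CPM (0.453, 0.412 to 0.498) and Ifit2 at 29.4 against 69.7 CPM (0.422, 0.363 to 0.490), with 15.1% of Rsad2 UMIs in 1 cell. The chemokine Cxcl10, itself induced by interferon, was at 33.8 against 99.98 CPM, and the neutrophil attractant Cxcl2 at 254 against 500 CPM. MHC class I genes were higher, with a median ratio of 1.17 (percentile 99.99) and 11 of 11 members above 1, among them H2-Q7 (25.9 against 15.96 CPM), Nlrc5 and the peptide transporter Tap1.

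MHC class II genes were higher in BAM-like cells as a whole, with a median ratio of 1.36 (percentile 100) and 9 of 9 members above 1. H2-Aa stood at 1744 against 1261 CPM, H2-Eb1 at 1355 against 968 CPM, and Ciita, the master regulator of the class, at 25.7 against 15.6 CPM. Inside the 4 larger clusters the median log2 ratios were 0.13, 0.11, 0.075 and -0.90 (percentiles 90.7, 80.5, 87.4 and 0), so none stood apart higher and 1 lower, while averaged over clusters with at least 200 cells the list's median was 0.11, less than the 0.44 of all BAM-like cells but still apart. At a mitochondrial limit of 20%, where the class lacks the MHC class II cluster, the list's median log2 ratio was 0.072 and no longer stood apart. Disease-associated genes had a median ratio of 1.14 (percentile 100), with the integrin Itgax at 11.9 against 3.62 CPM, the galectin Lgals3 at 83.4 against 28.3 CPM and the tetraspanin Cd9 at 142 against 79.0 CPM. At the 20% limit, in cells that again lack that cluster, the log2 ratios of Cd9 (-0.42) and H2-Aa (-0.041) turned. That list's direction turned at a mitochondrial limit of 20% (-0.073 on the log2 scale) and when averaged over clusters (-0.024), and it was not apart in thinned cells (0.092).

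Other lists in BAM-like cells stood closer to 1. Immediate-early genes had a median ratio of 0.876 (percentile 0), with the transcription factor Klf2 at 763 against 1184 CPM, and lysosomal genes one of 1.07 (99.2). Neither stood apart at a mitochondrial limit of 20% (-0.062 and 0.092 on the log2 scale), and the lysosomal list did not in thinned cells (0.085). Perivascular macrophage identity genes had a median ratio of 0.985 (33.1), with the lectins Cd209b (72.1 against 49.5 CPM) and Cd209f (689 against 553 CPM) higher and Lyve1 (664 against 813 CPM) lower. Cytokines and chemokines gave 1.01 (51.3), complement 1.01 (55.2), and vascular and trophic factors 1.02 (55.7), where the metalloprotease Mmp14 (14.7 against 7.36 CPM) and Pdgfb (72.6 against 49.4 CPM), a growth factor for mural cells, were higher and Hbegf (5.13 against 11.7 CPM) lower. Hypoxia and glycolysis gave 1.04 (66.6), oxidative phosphorylation 0.989 (23.4), cell cycle 0.99998 (31.2) and sex-linked genes 1.07 (77.8). Among 9365 genes, 28 were at least 2-fold higher and 17 lower, and without the cluster led by interferon genes (185 and 118 cells) the lower ones numbered 5. Over all alternatives these counts ran from 3 to 75 and from 1 to 33. By the ranking rule the higher genes were Gdpd3, Polr2l (46.4 against 26.4 CPM), Txnrd1 (21.5% of UMIs in 1 cell), Cd55, an inhibitor of complement (79.1 against 51.2 CPM), Ch25h, Afg3l1, Taf4, Gtpbp1, Batf3 and Usp35, and the lower ones Rsad2, Ifit2, Isg15, Ifit1, Cmpk2 (27.8% of UMIs in 1 cell), Cxcl2, Ifit3, H4f16, Oasl1 and Ifi208.

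**Figure D3:**
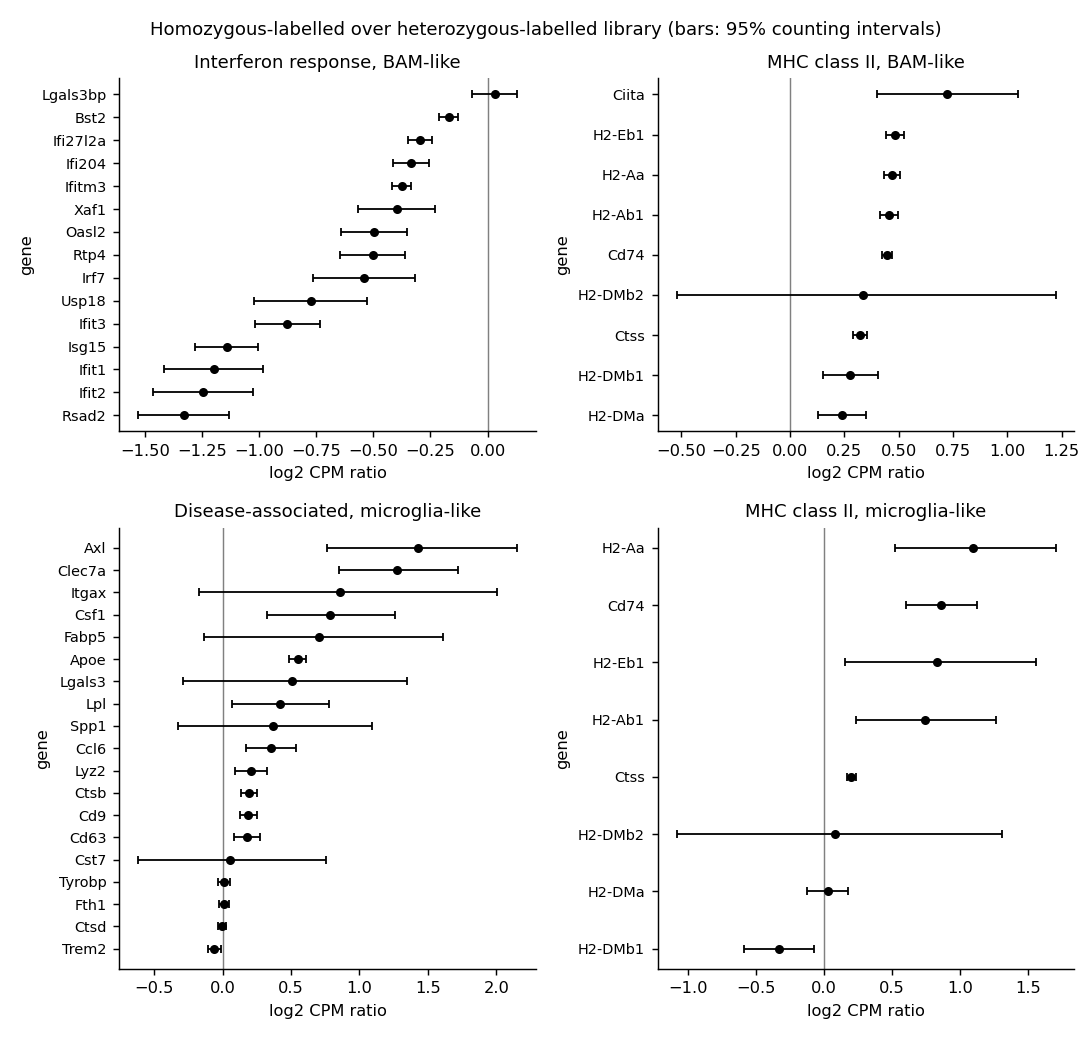
Log2 CPM ratio, homozygous-labelled over heterozygous-labelled, for members of 3 lists in BAM-like and microglia-like cells, with 95% counting intervals as bars and 15 of the 16 measured interferon-response genes drawn. In BAM-like cells 14 of those 16 lie below 0 and 9 of 9 MHC class II genes above, and in microglia-like cells 17 of 19 disease-associated genes lie above 0.

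Microglia-like cells of the homozygous-labelled library held less of the homeostatic signature and more of the disease-associated one. Homeostatic genes had a median ratio of 0.890 (percentile 0), with 13 of 18 below 1. The purinergic receptor P2ry12 was at 2429 against 2932 CPM (ratio 0.828, 0.803 to 0.855), the surface marker Tmem119 at 1081 against 1311 CPM (0.824, 0.786 to 0.865) and the fructose transporter Slc2a5 at 173 against 229 CPM (0.755, 0.672 to 0.849). Disease-associated genes had a median ratio of 1.28 (percentile 100), with 17 of 19 above 1. Axl, a receptor for apoptotic cells, was at 26.4 against 9.83 CPM (2.69-fold, 1.69 to 4.45), and Clec7a, a receptor for fungal glucans, at 60.1 against 24.8 CPM (2.42-fold, 1.81 to 3.30). Axl and another member, Lpl, are also among the leading genes of the MHC-II-high BAM-like cluster (330 and 441 cells). Whether free RNA from such cells added to this list in microglia-like cells was not tested.

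Antigen presentation and chemokine genes were higher in the same cells. MHC class II genes had a median ratio of 1.38 (percentile 100), with 4 of 8 at least 1.5-fold higher, H2-Aa at 30.03 against 14.1 CPM and the invariant chain Cd74 at 127 against 70.1 CPM. Those levels are far under that of H2-Aa in BAM-like cells (1744 against 1261 CPM), and the summed class II genes (209 against 115 CPM) were also higher in endothelial-like cells, at 136 against 72.1 CPM. MHC class I genes had a median ratio of 1.17 (99.9) and chemokines 1.12 (98.6), with Ccl4 at 882 against 447 CPM (14.9% of UMIs in 1 cell), Ccl3 at 398 against 219 CPM and Cxcl2 at 27.3 against 2.99 CPM. The chemokine list lost its standing in 6 alternatives, and the MHC class II list in 1 (0.18 on the log2 scale), where cells under 2000 UMIs (256 of 749 and 247 of 1029) were left out and the others thinned to that depth.

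The other microglia-like lists were lysosome at 1.06 (98.3), interferon response at 1.15 (96.2), complement at 1.04 (88.3), vascular and trophic factors at 1.06 (88.3), immediate-early genes at 1.02 (83.0), hypoxia and glycolysis at 1.04 (80.7), oxidative phosphorylation at 0.939 (2.95), cell cycle at 0.872 (10.3) and sex-linked genes at 1.01 (52.9). The MHC class I list lost its standing in 1 of 13 alternatives and the lysosomal list in 2. Of 6795 genes, 17 were at least 2-fold higher and 6 lower (1 to 52 and 1 to 27 over the alternatives). Ranked genes higher were Ccl4, Ccl3, Ly9 (36.6 against 16.7 CPM), Gng10, the kinase Tec, Ago4, Ptk2b, Arhgap24, Kcnj2 and Tnfsf13b. Ranked genes lower were Gp9 (24.8 against 52.1 CPM), Upk1b (19.3 against 41.9 CPM), Prkag1, Crybb1 (204 against 309 CPM), Cib1, Dcps, Snrnp40, Mak16, Slc2a8 and Hdac2.

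In endothelial-like cells, which line the vessels, the homozygous-labelled library was lower in immediate-early genes and higher in venous and barrier transport genes. Immediate-early genes had a median ratio of 0.697 (percentile 0), and 7 of 19 were at least 1.5-fold lower with none higher. The nuclear receptor Nr4a1 was at 28.6 against 76.6 CPM (ratio 0.373, 0.304 to 0.456), Btg2 at 181 against 350 CPM (0.517, 0.475 to 0.562) and Junb at 341 against 535 CPM (0.638, 0.599 to 0.679). Venous identity genes had a median ratio of 1.19 (percentile 100), with the chemokine receptor Ackr1 at 61.7 against 35.4 CPM, Lcn2 at 52.0 against 37.3 CPM and Il1r1 at 85.5 against 66.4 CPM, and the venous-like share was 11.8% against 9.91%. Averaged over the capillary-like clusters alone the venous list's log2 median was 0.089 and not apart, and Lcn2 turned there (-0.013) and at a mitochondrial limit of 5% (-0.032). Barrier transporters had a median ratio of 1.08 (99.7) with 17 of 19 above 1, among them the drug efflux pump Abcb1a (1208 against 1049 CPM) and Slc22a8 (328 against 269 CPM), while the amino acid transporter Slc7a5 was lower (299 against 392 CPM).

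Lower lists in endothelial-like cells were caveolae and transcytosis at 0.886 (percentile 0.43), with Plvap at 286 against 363 CPM and Ehd2, angiogenesis and tip cell genes at 0.906 (0.38), with the peptide Apln at 8.44 against 17.0 CPM and Esm1 at 93.3 against 135 CPM, vasoactive signalling at 0.914 (1.41), with Klf2 at 1531 against 2080 CPM, and hypoxia and glycolysis at 0.918 (1.33). Plvap and Esm1 mark the fenestrated-like cluster, and without it their log2 ratios were 0.20 and 1.01. With the same averaging, log2 medians turned to -0.049 for barrier transporters, 0.055 for caveolae and 0.14 for vasoactive signalling. MHC class I was at 1.13 (99.4). Of 14 alternatives the standing was kept in 5 for vasoactive signalling, 6 for MHC class I, 9 for hypoxia and glycolysis, 9 for caveolae (-0.095 on the log2 scale without the fenestrated-like cluster), 11 for angiogenesis and 13 each for barrier transporters and venous genes. Closer to random lists were Wnt targets such as Tnfrsf19, Foxf2 and Apcdd1 at 1.07 (96.5), junctions and basement membrane at 1.04 (93.4), activation at 1.06 (83.0, with Lrg1 at 27.3 against 40.2 CPM), interferon response at 0.949 (7.27), arterial identity at 0.960 (14.1, with Gkn3 at 147 against 212 CPM), oxidative phosphorylation at 0.962 (14.3), cell cycle at 0.981 (28.9) and sex-linked genes at 1.15 (97).

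Of 8820 genes in endothelial-like cells, 24 were at least 2-fold higher and 8 lower. The higher ones numbered 14 under TMM scaling, 12 under median of ratios and 12 at a mitochondrial limit of 5%, the lower ones 14 with doublets kept, and over all alternatives the counts ran from 3 to 81 and from 0 to 20. Ranked higher were Cyp2e1 (18.8 against 7.17 CPM, 2.63-fold, 1.76 to 4.01), Atp8b2 (31.2 against 16.6 CPM), Man1b1, Klf16, Tbc1d4 (114 against 75.8 CPM), the chaperone Hyou1, Tshz3, Zdhhc7 and Pknox1. The pituitary hormone gene Prl ranked ahead of them on 510 UMIs, 82.0% of them in 1 cell, against 0 in the heterozygous-labelled library, which allows up to 0.615 CPM. Ranked lower were Cd300lg (48.9 against 87.7 CPM), Tcim (81.8 against 139 CPM), the immediate-early gene Apold1 (156 against 251 CPM), Stc1, the circadian factor Dbp (31.0 against 54.9 CPM), Car8, Obi1, Ppp1r14b, Pdcd7 and Ulk4. Of these, Cd300lg and Car8 are among the leading genes of the fenestrated-like cluster, which held 140 cells against 213 in the heterozygous-labelled library.

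Mural-like cells, which wrap the capillaries and arterioles, were lower in immediate-early and contractile genes in the homozygous-labelled library. Contractile genes had a median ratio of 0.741 (percentile 0.02) and 13 of 15 below 1, with the smooth muscle genes Tagln at 318 against 997 CPM (ratio 0.319, 0.273 to 0.372), Acta2 at 528 against 1061 CPM (0.498, 0.437 to 0.568) and Tpm1 at 739 against 1097 CPM. Single cells held 16.7% of Tagln and 17.9% of Acta2 UMIs, and over members with at least 100 UMIs the list's median log2 ratio was -0.29 and not apart. In the settings where a smooth muscle subcluster was named, the pericyte share was higher in the homozygous-labelled library. The makeup of mural-like cells and the level per cell thus cannot be told apart for contractile genes, or for the pericyte genes below. Immediate-early genes had a median ratio of 0.377 (percentile 0), with 17 of 19 at least 1.5-fold lower, among them Fos at 267 against 1355 CPM, Junb at 151 against 668 CPM and Atf3 at 9.76 against 224 CPM, all 3 of which turned with doublets kept (0.16, 0.35 and 0.25 on the log2 scale). Without 1 subcluster that mixes in endothelial markers (25 of 184 and 24 of 343 cells) the list's median log2 ratio was -0.33 instead of -1.41, at percentile 0.05. In a separate clustering with doublets kept it was 0.057.

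Pericyte identity genes were higher in mural-like cells, at a median ratio of 1.31 (percentile 99.9), with the proline transporter Slc6a20a at 1195 against 640 CPM and the channel genes Abcc9 at 1611 against 1031 CPM and Kcnj8 at 916 against 632 CPM. Mural receptors were at 1.24 (98.9), with the endothelin receptor Ednra at 391 against 275 CPM and Pdgfrb at 2078 against 1522 CPM. Without the mixed subcluster these medians were 0.089 and 0.081 on the log2 scale and no longer apart, and the interferon list, at 0.741 (0.26), turned to 0.014. The pericyte and receptor lists kept their standing in 6 of 10 alternatives each and the interferon list in 5 of 9. Hypoxia and glycolysis was at 0.799 (0.55), oxidative phosphorylation at 0.909 (4.9), MHC class I at 0.932 (19.9), mural matrix at 1.16 (90.6) and sex-linked genes at 1.09 (63.3), and the cell cycle list had too few measured members. Of 2723 genes, 13 were at least 2-fold higher and 35 lower, against 33 and 21 with doublets kept and 7 and 8 without the mixed subcluster (2 to 62 and 8 to 70 over all alternatives). Ranked higher were Slc6a20a, Slc6a13, Gatm (755 against 425 CPM), Tcf7l2, Spp1, Atp2a3 (459 against 258 CPM), Tec, the antioxidant enzyme Sod3 (907 against 557 CPM), Abcc9 and Bgn, of which Slc6a20a, Slc6a13 and Bgn have their highest level in a fibroblast-like, Gatm in the oligodendrocyte-like, Tcf7l2 in the astrocyte-like and Spp1 in an unnamed cluster (12.6% of Spp1 UMIs in 1 cell). Ranked lower were Gadd45g, Tagln, Ly6a, Foxq1, Acvrl1, Acta2, Ly6c1, Id1, Jcad and Cavin3, of which Ly6a, Foxq1, Acvrl1, Ly6c1, Id1, Jcad and Cavin3 have their highest level in endothelial-like clusters. Without the mixed subcluster the log2 ratios of Ly6a (0.37), Ly6c1 (1.17) and Jcad (0.086) turned, and from 500 UMIs per cell so did those of Ly6c1 (1.46) and Jcad (0.37). Between 8.57% and 18.8% of the heterozygous-labelled UMIs of each of these lower genes lay in 1 cell.

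Fibroblast-like cells of the homozygous-labelled library were higher in transporter, matrix and myofibroblast genes and lower in immediate-early genes. Transporters and trophic factors had a median ratio of 1.33 (percentile 100), with the growth factor Bmp7 at 98.6 against 60.5 CPM (1.63-fold, 1.41 to 1.89) and the cystine transporter Slc7a11 at 860 against 587 CPM (1.47-fold, 1.40 to 1.54), whereas the alarmin Il33 was lower (182 against 236 CPM). Matrix genes had a median ratio of 1.12 (100) with 20 of 25 above 1, among them the proteoglycans Dcn (2922 against 2007 CPM) and Lum (228 against 148 CPM). Myofibroblast genes were at 1.26 (99.96), with Tagln at 87.6 against 45.3 CPM and, in the other direction, Ccn1 at 148 against 330 CPM. Immediate-early genes were at 0.781 (percentile 0), with Nr4a1 at 67.0 against 173 CPM and Btg2 at 196 against 360 CPM. The largest cluster held 49.9% of fibroblast-like cells in the heterozygous-labelled and 38.6% in the homozygous-labelled library, and averaged over clusters with at least 200 cells, which leaves that cluster alone, the log2 medians for matrix (0.026) and myofibroblast genes (0.14) were not apart and the log2 ratio of Slc7a11 turned (-0.45). The matrix list kept its standing in 10 and the myofibroblast list in 11 of 13 alternatives. Slc7a11, Slc6a13 and Slc22a6 of the transporter list are among the leading genes of another fibroblast-like cluster, with 191 and 347 cells.

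The remaining fibroblast-like lists were MHC class I at 1.12 (99.0), interferon response at 1.03 (76.4), hypoxia and glycolysis at 0.989 (38.2), oxidative phosphorylation at 0.960 (17.3), cell cycle at 1.05 (51.3) and sex-linked genes at 1.001 (50.1). The MHC class I list lost its standing in 3 of 13 alternatives, down to 0.032 on the log2 scale at a mitochondrial limit of 5%. Of 9441 genes, 18 were at least 2-fold higher and 12 lower, against 43 and 31 from 500 UMIs per cell, 31 and 26 at a mitochondrial limit of 20% and 59 higher with doublets kept (2 to 66 and 4 to 33 over all alternatives). Ranked higher were Krtdap (398 against 205 CPM, 17.3% of UMIs in 1 cell), Epyc, Moxd1, the adhesion molecule Vcam1 (84.7 against 47.1 CPM), Fzd8, the retinol carrier Rbp4 (206 against 130 CPM), Chad, Gap43 and Zfp874a. Dnase1 ranked ahead of them, with 98.2% of its 113 UMIs in 1 cell and 0 in the heterozygous-labelled library, which allows up to 0.679 CPM. Ranked lower were the nuclear receptors Nr4a3 (9.96 against 37.4 CPM) and Nr4a2 (67.3 against 164 CPM), Slc25a25 (46.05 against 122 CPM), Ccn1, Cebpd (220 against 419 CPM), Sik1, Gadd45g, Tcim, the opioid precursor Penk (514 against 809 CPM) and Fbxl15. At a mitochondrial limit of 5%, which left few cells, the log2 ratios of many of these genes turned, among the higher ones Moxd1 (-0.53), Vcam1 (-0.10), Rbp4 (-0.64), Lum (-0.12) and Tagln (-0.014), and among the lower ones Nr4a3, Sik1 and Tcim (0.74 each), Nr4a2 (0.16), Slc25a25 (1.16), Btg2 (0.14) and Penk (0.36). Epyc turned from 2000 UMIs per cell (-0.16) and Lum from 500 (-0.047). Krtdap, Chad and Gap43 are among the leading genes of a fibroblast-like cluster of 165 and 259 cells. Penk is among those of the largest cluster, which held 49.9% and 38.6% of fibroblast-like cells. Direction within clusters was checked in the largest cluster alone. For these 4 genes, cluster makeup and level per cell were therefore not separated.

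**Figure D4:**
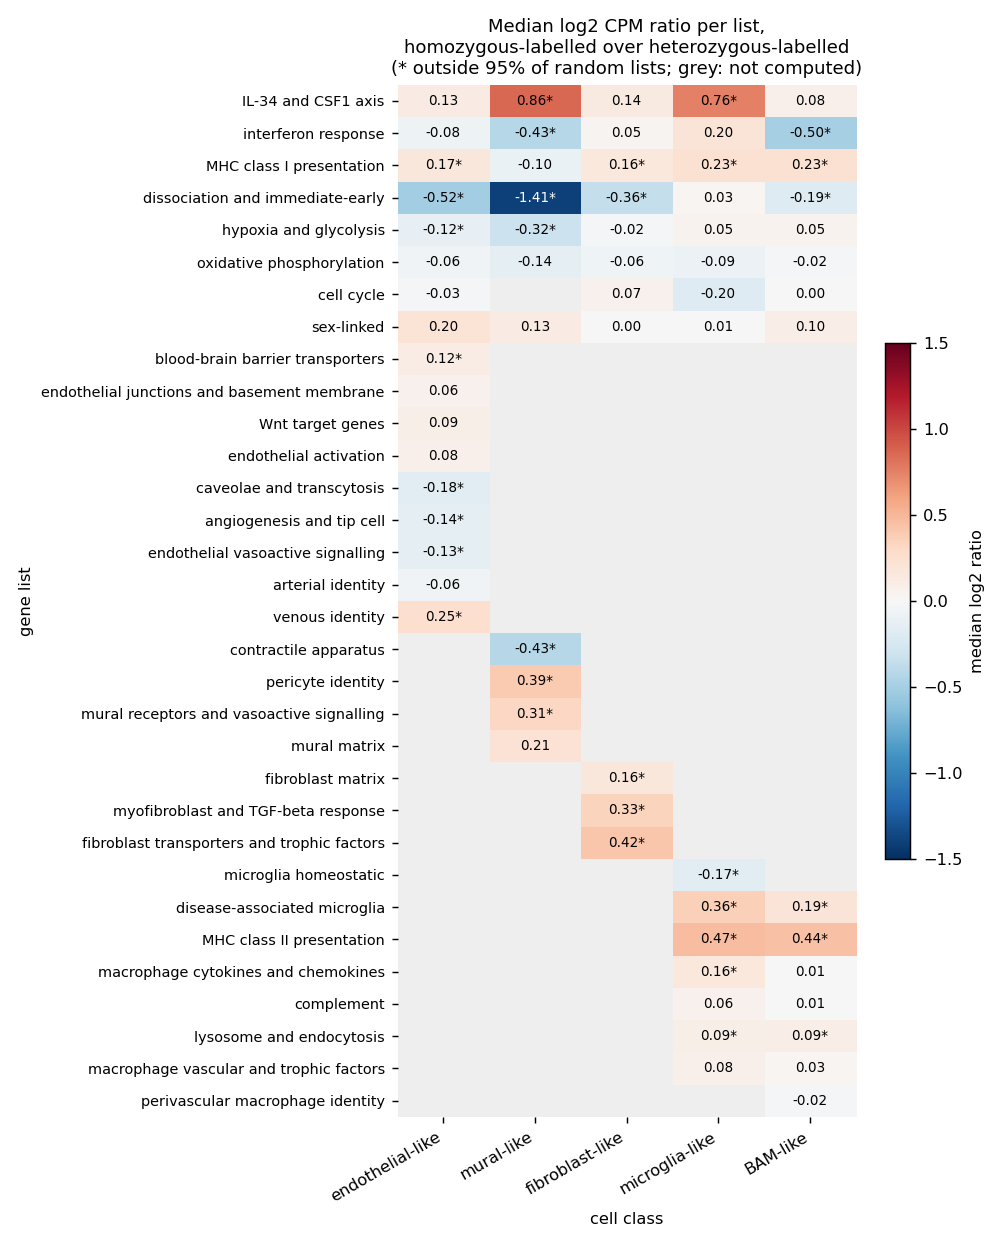
Median log2 CPM ratio of each gene list (vertical axis) in each cell class (horizontal axis), homozygous-labelled over heterozygous-labelled, with an asterisk where the list lies outside the central 95% of random lists. Values run from -1.41 for immediate-early genes in mural-like cells to 0.86 for the IL-34 and CSF1 axis there.

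Across the classes, lists that stood apart higher and lower numbered 3 and 5 of 17 in endothelial-like, 3 and 4 of 11 in mural-like, 4 and 1 of 11 in fibroblast-like, 6 and 1 of 15 in microglia-like and 4 and 2 of 15 in BAM-like cells. The Y-linked genes of the sex-linked list were detected in both libraries in all 5 of these classes, and the list stood apart in none of them, with Ddx3y at 176 and 177 CPM in endothelial-like cells. Transcripts of Ttr, an abundant product of choroid plexus epithelium, were lower in the homozygous-labelled library in every main class, with ratios of 0.481 in BAM-like, 0.494 in microglia-like, 0.613 in endothelial-like, 0.631 in fibroblast-like and 0.362 in mural-like cells, and 0.957 in choroid plexus epithelial-like cells themselves. At least 2-fold differences in genes kept by a free RNA guard over all clusters numbered 6 higher and 0 lower in endothelial-like, 5 and 9 in mural-like, 6 and 9 in fibroblast-like, 5 and 2 in microglia-like and 3 and 1 in BAM-like cells.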

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

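The tests of explanations given here, on interferon-response and immediate-early genes, were chosen only after the results were seen. Several cell types that no sorting gate targeted were abundant. Choroid plexus epithelial-like cells made up 10.6% of cells in the heterozygous-labelled and 4.83% in the homozygous-labelled library. Neuron-like cells made up 4.82% and 8.34%, and ependymal-like cells 1.55% and 2.77%. Transcripts of tissues outside the brain's vessels also appeared, with 15372 UMIs of Prl, a pituitary hormone gene, in the homozygous-labelled library against 0 in the other. Of these, 14189 lay in 1 unnamed cluster. Bglap, a bone matrix gene, gave 4104 UMIs in the heterozygous-labelled library, 1735 of them in 1 cell, and 519 in the other.

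Interferon-response genes pointed in opposite directions in different cell types, with a median log2 ratio of -0.50 in BAM-like cells and 0.52 in neuron-like cells, where 13 of 13 measured members lay above 1. The difference between these cell types was not tested. A smaller BAM-like cluster led by interferon genes (185 and 118 cells) leaves the lower level in BAM-like cells unexplained as a whole, since without it the median was -0.30 (-0.44 to -0.20 over resampled cells), at percentile 0. Less free RNA from interferon-led cells would lower the list in microglia-like cells too, where it was 0.20, but 1 class cannot decide this. Outside BAM-like cells the list stood apart lower in mural-like (-0.43) and choroid plexus epithelial-like cells (-0.14) and higher in neuron-like cells (0.52). An unnamed cluster led by interferon genes held 20 cells in the heterozygous-labelled and 59 in the homozygous-labelled library. What stays open is free RNA, the genotype, which was not tested, and any difference in how the BAM gate was handled. Each may have set part of the -0.30 that remained.

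Immediate-early genes, which respond within minutes to stress and tissue handling, had a median log2 ratio of -0.52 in endothelial-like cells and 0.54 in choroid plexus epithelial-like cells, and the difference between them was not tested. If handling of the whole suspension moved these genes one way in every cell type, the 0.54 in choroid plexus epithelial-like cells would run against it as the whole cause. Whether cell types respond alike to handling was not tested, so a difference in handling between the suspensions stays open. In mural-like cells the median was -0.33 without the subcluster mixed with endothelial markers (percentile 0.05), with an interval over resampled cells of -0.77 to 0.28 that reaches past random lists, so the makeup of that subcluster and the level per cell cannot be told apart there. The median in mural-like cells was 0.057 with doublets kept. Handling that differed between gates, and the genotype itself, could each give lower values in endothelial-like, mural-like and fibroblast-like cells, and with 1 library per genotype neither was tested.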

How the results depend on the processing

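Of the alternatives described here, those without subtype markers, without the interferon-led BAM-like cluster, without the mixed mural-like subcluster, without the fenestrated-like cluster, without the top cell of each gene and under the free RNA guard were chosen only after the results were seen. The values kept their direction and their standing against random lists in all 14 alternatives for the interferon list (-0.53 to -0.30) and the MHC class I list (0.19 to 0.27) of BAM-like cells and for immediate-early genes of endothelial-like cells (-0.62 to -0.25). They did so in all 13 for microglia-like homeostatic (-0.20 to -0.15) and disease-associated genes (0.18 to 0.37), and for fibroblast-like immediate-early genes (-0.41 to -0.22) and transporters (0.15 to 0.49). Some of these alternatives could not have changed a standing. Each other scaling shifts every ratio of a class alike, and averaging over clusters repeats the main value in microglia-like cells, which form 1 cluster. The totals that follow include such values. Of the list medians that answer a comparison, 339 values kept their standing under an alternative, 70 did not and 8 turned. Of the counts of genes at least 2-fold apart, 82 stayed within 1.5 times the main count, 43 were lower and 23 higher. Of the shares, 72 moved by less than their counting interval and 16 by more. Of the values of single genes, 2853 moved by less than their interval, 451 by more and 51 turned. Lists that did not stand apart in the main run did so in 35 of their values. Leiden resolution 2 and totals without mitochondrial and ribosomal protein genes changed none of the calls they were run on. The largest shift of a class by another scaling was -0.059 on the log2 scale, in endothelial-like cells under median of ratios. Mural-like values could not be computed from 2000 UMIs per cell (49 and 138 cells), at a mitochondrial limit of 5% (44 and 66 cells) or with cells thinned (69 and 147 cells), and averaging over clusters used 0 mural-like, 2 endothelial-like, 3 BAM-like and 1 fibroblast-like and microglia-like cluster. No main value exists for the pericyte share, which was 86.5% and 92.9% from 500 UMIs per cell, 83.8% and 89.4% with doublets kept, 87.7% and 93.0% at Leiden resolution 2, and 84.8% and 90.6% without subtype markers. Astrocyte-like cells were too few in every setting. No paired analysis was possible because each genotype has 1 library and no label pairs them. Of the 5 classes compared, depth limits mural-like genes most, with 468588 and 819920 UMIs in all, so that only 2723 genes reached 100 UMIs. The gene minimum lowers or raises the counts by admitting fewer or more genes. For the other values that follow, the cause was not tested. List medians and gene ratios are on the log2 scale, and "turned" means that the sign changed, while other list medians no longer stood apart.

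At a mitochondrial limit of 5%, log2 share ratios were -0.45 for endothelial-like, 0.23 for mural-like, 0.10 for microglia-like, -0.13 for BAM-like, -0.10 for BAM-like of microglia-like and BAM-like cells, -0.039 for Lyve1-high of BAM-like cells and 0.12 for capillary-like of endothelial-like cells. Counts of genes at least 2-fold higher numbered 12 in endothelial-like and 11 in BAM-like cells, and those lower 24 in fibroblast-like, 3 in microglia-like and 8 in BAM-like cells. Endothelial-like list medians were 0.072 for MHC class I, -0.093 for hypoxia and glycolysis and -0.100 for vasoactive signalling. Fibroblast-like list medians were 0.032 for MHC class I and 0.078 for matrix. Microglia-like list medians were 0.49 for the IL-34 and CSF1 axis. Single genes in endothelial-like cells turned to -0.032 for Lcn2. Single genes in fibroblast-like cells turned to 0.14 for Btg2, 0.16 for Col5a2 and Nr4a2, -0.21 for Csf1, 0.27 for Fbln1, -0.12 for Lum, -0.53 for Moxd1, 0.74 for Nr4a3, Sik1 and Tcim, 0.36 for Penk, -0.64 for Rbp4, 1.16 for Slc25a25, -0.014 for Tagln and -0.10 for Vcam1.

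At a mitochondrial limit of 20%, log2 share ratios were -0.42 for BAM-like and -0.27 for BAM-like of microglia-like and BAM-like cells. Counts of genes at least 2-fold higher numbered 28 in mural-like, 31 in fibroblast-like and 9 in BAM-like cells, and those lower 63 in mural-like, 26 in fibroblast-like and 3 in microglia-like cells. Endothelial-like list medians were -0.094 for caveolae and -0.035 for vasoactive signalling. Mural-like list medians were 0.53 for the IL-34 and CSF1 axis. Microglia-like list medians were 0.090 for cytokines and chemokines. BAM-like list medians were -0.062 for immediate-early genes, 0.072 for MHC class II and 0.092 for lysosome. BAM-like list medians turned to -0.073 for disease-associated genes. Single genes in mural-like cells turned to -0.27 for Csf1r. Single genes in fibroblast-like cells turned to -0.14 for Timp1. Single genes in BAM-like cells turned to -0.42 for Cd9 and -0.041 for H2-Aa.

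From 500 UMIs per cell, genes at least 2-fold higher numbered 43 in fibroblast-like cells, and those lower 13 in mural-like and 31 in fibroblast-like cells. Endothelial-like list medians were 0.15 for MHC class I and -0.059 for vasoactive signalling. Mural-like list medians were 0.55 for the IL-34 and CSF1 axis, -0.11 for interferon response, 0.12 for pericyte identity and 0.14 for mural receptors. Fibroblast-like list medians were 0.039 for matrix and 0.14 for myofibroblast genes. Microglia-like list medians were 0.14 for cytokines and chemokines. Single genes in mural-like cells turned to -0.019 for Cspg4, 0.37 for Jcad, 1.46 for Ly6c1 and 0.12 for Slc2a1. Single genes in fibroblast-like cells turned to -0.047 for Lum.

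From 2000 UMIs per cell, log2 share ratios were 1.20 for mural-like and 0.37 for microglia-like. Counts of genes at least 2-fold higher numbered 8 in microglia-like cells. Endothelial-like list medians were 0.080 for MHC class I, -0.083 for hypoxia and glycolysis and -0.11 for vasoactive signalling. Microglia-like list medians were 0.036 for cytokines and chemokines. Single genes in fibroblast-like cells turned to -0.16 for Epyc.

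With doublets kept, genes at least 2-fold higher numbered 33 in mural-like and 59 in fibroblast-like cells, and those lower 14 in endothelial-like, 21 in mural-like and 2 in microglia-like cells. Endothelial-like list medians were 0.12 for MHC class I, -0.080 for hypoxia and glycolysis and -0.032 for vasoactive signalling. Mural-like list medians were 0.50 for the IL-34 and CSF1 axis, -0.058 for interferon response, 0.081 for pericyte identity and 0.074 for mural receptors. Microglia-like list medians were 0.092 for cytokines and chemokines. Mural-like list medians turned to 0.057 for immediate-early genes. Single genes in mural-like cells turned to 0.25 for Atf3, 0.027 for Bst2, -0.0091 for Cspg4, 0.16 for Fos, 0.017 for Hspb1 and 0.35 for Junb.

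At Leiden resolution 0.5, log2 share ratios were 0.55 for fibroblast-like, -0.41 for BAM-like and -0.25 for BAM-like of microglia-like and BAM-like cells.

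Without subtype markers among the variable genes, log2 share ratios were -0.40 for BAM-like and -0.23 for BAM-like of microglia-like and BAM-like cells.

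Under TMM scaling, genes at least 2-fold higher numbered 14 in endothelial-like cells.

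Under median-of-ratios scaling, genes at least 2-fold higher numbered 12 in endothelial-like cells.

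With equal weight per cell, genes at least 2-fold lower numbered 3 in microglia-like cells. List medians of endothelial-like cells were -0.037 for caveolae and -0.034 for angiogenesis. Mural-like list medians were 0.34 for the IL-34 and CSF1 axis, -0.29 for interferon response, 0.17 for pericyte identity and 0.13 for mural receptors. Fibroblast-like list medians were 0.13 for MHC class I. List medians of microglia-like cells were 0.39 for the IL-34 and CSF1 axis, 0.16 for cytokines and chemokines and 0.067 for lysosome. Endothelial-like list medians turned to 0.030 for vasoactive signalling. Single genes in fibroblast-like cells turned to -0.15 for Timp1.

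With cells under 2000 UMIs left out and the others thinned to 2000 UMIs, genes at least 2-fold higher numbered 14 in endothelial-like, 10 in fibroblast-like, 8 in microglia-like and 9 in BAM-like cells, and those lower 3 in microglia-like and 5 in BAM-like cells. List medians of endothelial-like cells were 0.11 for MHC class I, -0.090 for hypoxia and glycolysis, -0.15 for caveolae, -0.077 for angiogenesis and -0.082 for vasoactive signalling. Fibroblast-like list medians were 0.15 for MHC class I. List medians of microglia-like cells were 0.14 for MHC class I, 0.18 for MHC class II and 0.081 for lysosome. BAM-like list medians were 0.092 for disease-associated genes and 0.085 for lysosome. Fibroblast-like gene ratios turned to -0.11 for Timp1. Single genes in microglia-like cells turned to 0.014 for Trem2.

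Averaged over clusters, genes at least 2-fold higher numbered 66 in fibroblast-like cells, and those lower 13 in endothelial-like and 20 in fibroblast-like cells. List medians of endothelial-like cells were 0.093 for MHC class I, -0.096 for hypoxia and glycolysis, -0.033 for angiogenesis and 0.089 for venous identity. Fibroblast-like list medians were 0.026 for matrix and 0.14 for myofibroblast genes. Endothelial-like list medians turned to -0.049 for barrier transporters, 0.055 for caveolae and 0.14 for vasoactive signalling. BAM-like list medians turned to -0.024 for disease-associated genes. Single genes in endothelial-like cells turned to -0.15 for Csf1, -0.013 for Lcn2, 0.37 for Ptgs1 and -0.067 for Vwf. Fibroblast-like gene ratios turned to -0.45 for Slc7a11 and -0.28 for Timp1. Single genes in BAM-like cells turned to -0.15 for Ier3 and -0.079 for Zfp36.

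From 50 UMIs per gene, genes at least 2-fold higher numbered 81 in endothelial-like, 62 in mural-like, 54 in fibroblast-like, 52 in microglia-like and 75 in BAM-like cells, and those lower 20 in endothelial-like, 70 in mural-like, 33 in fibroblast-like, 27 in microglia-like and 33 in BAM-like cells.

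From 500 UMIs per gene, genes at least 2-fold higher numbered 3 in endothelial-like, 2 in mural-like, 2 in fibroblast-like, 1 in microglia-like and 5 in BAM-like cells, and those lower 3 in endothelial-like, 8 in mural-like, 4 in fibroblast-like, 1 in microglia-like and 7 in BAM-like cells.

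With members of at least 100 UMIs, list medians of endothelial-like cells were 0.10 for MHC class I. Mural-like list medians were -0.29 for contractile genes.

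Under the free RNA guard, genes at least 2-fold higher numbered 6 in endothelial-like, 5 in mural-like, 6 in fibroblast-like, 5 in microglia-like and 3 in BAM-like cells, and those lower 0 in endothelial-like, 9 in mural-like, 2 in microglia-like and 1 in BAM-like cells.

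Without the top cell per gene, genes at least 2-fold lower numbered 2 in microglia-like cells. List medians of microglia-like cells were 0.17 for cytokines and chemokines.

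Without the interferon-led BAM-like cluster, genes at least 2-fold lower numbered 5 in BAM-like cells.

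Without the mixed mural subcluster, genes at least 2-fold higher numbered 7 in mural-like cells, and those lower 8 in mural-like cells. List medians of mural-like cells were 0.58 for the IL-34 and CSF1 axis, 0.089 for pericyte identity and 0.081 for mural receptors. Mural-like list medians turned to 0.014 for interferon response. Single genes in mural-like cells turned to 0.20 for Bst2, -0.032 for Cspg4, 0.014 for Ifitm3, 0.086 for Jcad, 0.37 for Ly6a and 1.17 for Ly6c1.

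Without the fenestrated-like cluster, genes at least 2-fold higher numbered 10 in endothelial-like cells. List medians of endothelial-like cells were 0.090 for MHC class I, -0.095 for caveolae and -0.019 for vasoactive signalling. Single genes in endothelial-like cells turned to 1.01 for Esm1 and 0.20 for Plvap.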

Other observations

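The tests on MHC class II genes and on the genes around Il34 were chosen only after results were seen, and the cell types described next were picked after their values were seen. Neuron-like cells of the homozygous-labelled library were higher in interferon-response and MHC class I genes, with median ratios of 1.44 (percentile 99.8) and 1.55 (99.99), and 8 of 8 measured MHC class I members lay above 1. Their oxidative phosphorylation genes had a median ratio of 0.883 (0.74), with 13 of 18 below 1. Of 7945 genes in these cells, 34 were at least 2-fold higher and 14 lower, led among the higher ones by Gh and Prl, pituitary hormone genes, and by Bpifa1, of whose UMIs 99.2% lay in 1 cell. Genes with a known neuronal role included the potassium channel Kcna6 (55.6 against 23.6 CPM) and the splicing factor Rbfox2 (667 against 393 CPM), both higher, and the GABA receptor subunit Gabra2 (94.7 against 189 CPM), lower.

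Choroid plexus epithelial-like cells, the source of cerebrospinal fluid, were higher in immediate-early genes, at a median ratio of 1.45 (percentile 100) with 18 of 19 above 1, and lower in interferon-response genes, at 0.909 (0.15). Of 8786 genes there, 15 were at least 2-fold higher and 5 lower, with Apoc1, an apolipoprotein gene, at 72.5 against 41.3 CPM and Defb11, a defensin gene, at 172 against 103 CPM. Ependymal-like cells, which line the ventricles, had a higher median for immediate-early genes too (1.44, percentile 100, 15 of 19 above 1) and lower oxidative phosphorylation genes (0.940, percentile 1.24). The unnamed cluster nearest to fibroblasts held 710 and 866 cells and was led by Ccn3, Bche and Bmp4. Like fibroblast-like cells it was lower in immediate-early genes (0.719, percentile 0) and higher in MHC class I genes (1.17, percentile 99.9), and it was higher in Thbs1, a matrix glycoprotein gene (612 against 369 CPM). Unlike them (1.05, percentile 51.3) it was lower in cell cycle genes (0.757, percentile 0.715, 6 of 7 below 1). Its Bglap UMIs came almost wholly from 1 cell (99.3%).

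Blood-lineage cells, whose shares follow the sort, made up more of the homozygous-labelled library, within counting error for erythroid-like cells. Monocyte-like cells made up 1.83% against 1.21% of cells, neutrophil-like cells 1.33% against 0.830%, T or NK cell-like cells 0.628% against 0.391%, B cell-like cells 0.911% against 0.452% and cycling cells, led by myeloid precursor genes such as Elane and Mpo, 1.21% against 0.660%. Oligodendrocyte-like cells made up 1.77% against 1.17%, and erythroid-like cells 0.492% against 0.452%. These calls depend on the filter. At a mitochondrial limit of 5% the ratios of B cell-like (1.15, 0.595 to 2.21), T or NK cell-like (1.34, 0.783 to 2.29), cycling (1.40, 0.942 to 2.07) and oligodendrocyte-like shares (1.67, 0.904 to 3.07) lay within counting error, and from 500 UMIs per cell that of erythroid-like cells did not (2.34, 1.65 to 3.31). Pomc, another pituitary gene, gave 15726 UMIs in the homozygous-labelled and 403 in the heterozygous-labelled library, and Gh gave 6208 and 2.

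MHC class II genes were higher in microglia-like cells (summed 209 against 115 CPM). More free RNA from cells rich in these genes would raise them in every class, and 3 of 5 non-immune classes lay above 1 beyond counting error (endothelial-like 1.89, fibroblast-like 1.26 and neuron-like 1.51). Fibroblast-like cells held 1170 against 932 CPM, far above the microglia-like level, so their ratio says little about free RNA. Mural-like cells were at 1.49 (0.996 to 2.26) and choroid plexus epithelial-like cells at 0.638, so free RNA and expression in microglia-like cells cannot be told apart. BAM-like cells among the microglia-like ones would bring BAM markers, whose median log2 ratio was 0.13 (percentile 74.5), too close to the middle of random lists to decide. The genotype stays open as well, as it was not tested.

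DNA of another strain flanking the targeted locus could shift genes near Il34. In endothelial-like cells, the 93 genes within 10 Mb of Il34 had absolute log2 ratios at percentile 30.6 of random gene sets, and the 135 genes within 15 Mb at percentile 33.6. As a set, genes around the locus thus differed no more than others in endothelial-like cells, a negative result for the set. A median would not show a few differing genes, and the heterozygous-labelled library carries the allele too. Whether single genes near Il34 shift is therefore not settled, and sequence differences stay unexamined.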
